A study of Danio rerio with 18 samples.

How the data were processed

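RNA from pools of zebrafish embryos was hybridised to Agilent 44K expression arrays read in Cy3 and Cy5. The 18 samples form 6 groups of 3, and per the labels each pool held 60 to 100 embryos at 4.7 hours post fertilization. MZ embryos are maternal-zygotic for the m793 allele of spg, the gene now called pou5f3 and in the labels pou5f1. WT embryos came from AB and TÜB fish. Cycloheximide (CHX) blocks protein synthesis and was given at 15 µg/ml from 1.5 hours post fertilization. The injected mRNA was 100 pg of Pou5f1 or 50 pg of Sox2 per embryo. The groups are uninjected MZ, MZ with Pou5f1, WT with CHX, MZ with CHX, MZ with CHX and Pou5f1, and WT with CHX and Sox2.

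Values came from the deposited scanner files, whose unit is intensity per the file headers. The authors made them with Feature Extraction 9.5.3.1, which subtracted the background and normalized the dyes within each array. Its protocol was GE2-v5_95_Feb07 for slides 3 and 4, with multiplicative detrending, and GE2-v5_95_zeb_3 for slides 1 and 2, without it. The headers also show that slide 2 was scanned without extended dynamic range. Saturated probes numbered 44 and 6 in WT with CHX, replicates 1 and 2, and 216 and 249 in the same replicates of MZ with CHX, with 0 in every other sample. Per the series text, the authors split the channels, quantile normalised them and used them for independent comparisons.

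The 18 samples lie on 12 arrays of 4 slides. Arrays 1 to 3 (slide 1) carry MZ with Pou5f1 in Cy3 and MZ with CHX and Pou5f1 in Cy5. Arrays 5 and 6 (slide 2) and array 4 (slide 1) carry WT with CHX in Cy3 and MZ with CHX in Cy5, array 4 being replicate 3. Arrays 7 to 9 (slide 3) carry MZ in Cy5, and arrays 10 to 12 (slide 4) carry WT with CHX and Sox2 in Cy3. The other channels of slides 3 and 4, 6 in number, are not samples here and were not used. MZ and the Sox2 group share no slide with any other group.

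Each sample was its own channel's processed signal. Control spots (1417) and spots marked as outliers in the files were left out, the 2 spots of each of 21495 probes were averaged, and the 18 samples were quantile normalized and converted to log2. A gene was represented by its probe with the highest mean signal, giving 17985 genes, of which 2656 had several probes. Among those tested, probes of one gene differed in sign in 30.4% of genes for Pou5f1 without CHX, 32.2% for Pou5f1 with CHX, 32% for MZ against WT, 35.1% for Sox2, 30.5% for CHX in MZ and 23.5% for CHX with Pou5f1. Genes were named 306 times with all 18 samples, as named genes, list members or overlap genes, 123 times with several probes. In 98 of these at least 2 probes lay well above background in all samples of a group, and the others were not compared. Probes differed in sign in 7 and by over 2-fold each way in 1 (il17rd for Sox2). Without array 4 these numbers were 489, 184, 147, 11 and 1. Names were updated from a table of current symbols (7323 probes by accession, 598 by symbol, 2352 by older symbol) and 11222 kept the name in the files. Positions are those of the files, on build danRer2 (Zv4), and probes unplaced in that build are given without a chromosome.

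Tests used limma 3.58.1 in R 4.3.3 with statmod 1.5.0, data.table (version 1.17.8) and jsonlite 2.0.0. The design, the comparisons, the gene lists and the naming rule were fixed before the data were examined. The fit had 6 group means, the array as a random block (estimated correlation -0.098, or 0.315 without array 4) and an intensity trend in the variance. P values were two-sided and adjusted by Benjamini-Hochberg over the genes tested in a comparison, with a threshold of 0.05. A gene was tested when it lay well above background in all 3 samples of at least 1 of the groups compared and was measured in at least 2 samples of each. Errors of log2 changes are standard errors of the fit, and errors of group means are SDs.

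For each comparison the text names the 12 largest rises and the 12 largest falls among genes that passed, had replicate values that did not overlap between the groups, lay well above background in all 3 samples of a group, were not saturated throughout and carried an informative symbol. Non-overlap was not asked of the interaction. In 3 against 3 samples without any difference, values do not overlap in 10% of genes, and the smallest exact p is 0.1. The genes pou5f3 and sox2 are always given. A few genes that the rule names are not reported here. For overlaps up to 12 genes are named by the larger of their adjusted p values, and for each list up to 4 members with the smallest adjusted p. Where a gene was well above background in no sample of the lower group, the change is given as "at least" a fold, with each signal of that group raised to the dimmest one well above background in its sample if it lay below it. Where only some samples of the lower group were well above background, the change is printed as fitted and is not exact.

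There were 21 lists. Those of cell types cover the enveloping layer, the yolk syncytial layer, the germline, mesendoderm, the organizer, ventral genes and neuroectoderm. The others cover Pou, SoxB1 and Klf factors, FGF response, Wnt response, Notch and her genes, Hox and late patterning genes, maternal mRNAs, immediate early genes, stress and unfolded protein response, p53, cell cycle, ribosomal proteins, ribosome biogenesis, translation factors and histones. Each list was tested with cameraPR on the moderated t with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals. Of 147 tests with all 18 samples, 52 passed with the preset correlation and 4 with the estimated one, and 58 and 14 without array 4. Beside the members that passed among all genes, the text gives the number that passed when adjusted over the list alone.

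The pipeline was tested on simulated data with 200 changed genes. For Pou5f1 with CHX it recovered 18.8% of 2-fold, 68.8% of 4-fold, 91.7% of 8-fold and 98% of 16-fold changes, and 9 unchanged genes passed. Without array 4 these were 27.1%, 44.7%, 70.8% and 95.7%, with 4 unchanged genes. For Sox2 they were 39.4%, 78.8%, 94.1% and 100%, with 5 unchanged genes. Every run took its noise from the residuals of all 18 samples, array 4 included, and a preset array correlation unlike the estimated ones. The values without array 4 therefore do not show how well the real fit without it recovers changes. A list of 30 genes moved by 1 log2 unit passed with cameraPR, and 5 of 200 unmoved lists had p under 0.05. The noise was drawn for each gene on its own. These lists therefore do not show how the test behaves when members vary together.

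The deposited series matrix served as an alternative. Its values are in intensity units, per the deposited values themselves, and were normalized by the authors in 2 sets, of 6 samples without CHX and 12 with CHX. The column medians were 59.04, 59.05 and 59.04 for MZ, 59.13, 59.15 and 59.14 for MZ with Pou5f1, 37.45, 37.41 and 37.25 for WT with CHX, and 37.2, 37.21 and 37.23 for MZ with CHX. They were 37.26, 37.27 and 37.25 for MZ with CHX and Pou5f1, and 37.23, 37.23 and 37.29 for Sox2. The scale on which the 2 sets relate to each other stays unknown, so comparisons across them were not run on the matrix. Other alternatives were normexp background correction with an offset of 50, scaling to the 75th percentile, no filter or a stricter filter on dim probes, outlier spots kept and the mean over probes. The model was also fitted with no array block, with a replicate or slide block, with only the groups compared, with sample weights, with within-array log ratios and without each of the 18 samples in turn. Alternatives chosen after seeing the data were array 4 left out, array 4 and the Sox2 samples left out, MZ replicates 1 and 2 averaged, slide 1 alone and slide 2 alone.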

Results

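Expression was measured in 18 samples of zebrafish blastulae in 6 groups of 3. Between 36.3% and 66.2% of probes lay well above background in a sample. The share was 60.4% to 66.2% in MZ, 56.2% to 58.4% in MZ with Pou5f1, 43.2% to 56.2% in WT with CHX, 58.4% to 62.7% in MZ with CHX, 59.3% to 61.1% in MZ with CHX and Pou5f1, and 36.3% to 48.7% with Sox2. The SD of the log2 difference between the spots of a probe was 0.479 to 0.568 in the Sox2 samples and at most 0.425 elsewhere. The number of arrays, 3 samples per group, limits the precision of every value.

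The mutated gene itself, pou5f3 (chromosome 16, 27995572 to 27995631), was read in every sample. Its log2 signal was 15.13, 15.24 and 14.97 in MZ, 16.35, 16.07 and 15.9 in MZ with Pou5f1, and 15.099, 15.51 and 14.26 in WT with CHX. It was 14.47, 15.04 and 15.8 in MZ with CHX, 16.09, 16.01 and 15.86 in MZ with CHX and Pou5f1, and 14.92, 15.44 and 15.04 with Sox2. The transcript of the m793 allele was thus still detected in mutants, and as labelled the signals of WT and MZ with CHX overlapped. On arrays 5 and 6 WT was higher, and on array 4 it was lower. The log2 signal of sox2 (chromosome 7, 20803123 to 20803182) was 8.65, 8.99 and 8.4 in the Sox2 samples and 4.01, 4.85 and 4.96 in WT with CHX. The gene sox2 was not tested there, since only 2 of 3 samples with Sox2 and 1 of 3 without it lay well above background; the group means were 8.68 ± 0.29 and 4.60 ± 0.52 (SD, n = 3).

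**Figure D1:**
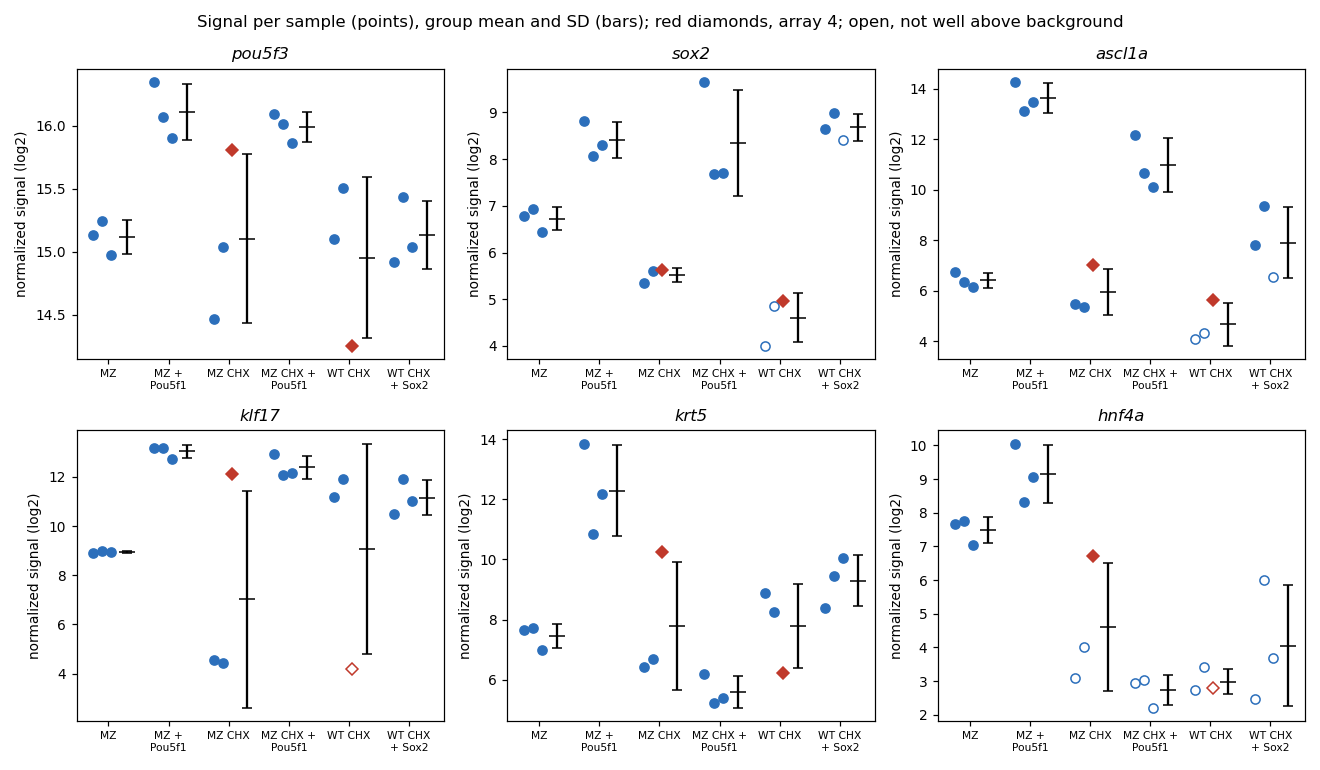
Log2 signal of 6 genes in every sample, with group means and SDs. Red diamonds mark the samples of array 4, and open symbols lie not well above background.

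The samples labelled WT with CHX replicate 3 and MZ with CHX replicate 3 share array 4 and stood apart from their groups. For klf17 (chromosome 2, 31268190 to 31268249) the log2 signal in WT with CHX was 11.17 and 11.9 in replicates 1 and 2 and 4.17 in the sample labelled replicate 3. In MZ with CHX it was 4.56, 4.42 and 12.12 in the same order. Comparisons that use either group are therefore given with all 18 samples and also without array 4, an alternative chosen after seeing the data.

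Injection of Pou5f1 mRNA into MZ embryos without CHX asks which genes respond to the returned factor, directly or through later steps. The largest rise was in ascl1a, a proneural transcription factor gene (chromosome 4, 17876001 to 17876060), from 6.41 ± 0.30 to 13.64 ± 0.59 (log2, SD, n = 3), which is 150-fold (log2 change 7.23 ± 0.70, adjusted p = 1e-04). The transcription factor genes that rose with it included sp5l (5.63 ± 1.19, chromosome 23), foxb1b (5.58 ± 1.17), insm1b (5.12 ± 0.70) and sox2 (1.68 ± 0.47, adjusted p = 0.033). The rises also included tmsb1 (6.06 ± 1.27, chromosome 14), pah (6.06 ± 0.66, chromosome 4), pitpnc1b (5.89 ± 1.03, chromosome 25), epyc (5.57 ± 1.38), dnase1l1 (5.09 ± 0.91), rgs4 (5.01 ± 1.13), polr3gla (4.91 ± 1.32) and tagln2 (at least 45.3-fold). The eye and forebrain gene six3b fell at least 3.72-fold, as did fgf13b (-4.78 ± 1.20), tbx2a (-3.17 ± 0.81) and nr4a2b (-2.90 ± 0.80). Further falls were those of slc35c2 (-4.13 ± 1.14), trpc4apb (-2.91 ± 0.46), atp1a1b (-2.81 ± 0.86), bgnb (-2.75 ± 0.71), ptgs1 (at least 7.25-fold), mtnr1aa (at least 3.56-fold; adjusted p = 0.056 without array 4) and sat2a.2 (at least 3.29-fold). The changes of dnase1l1, slc35c2 and bgnb are not exact, since only 1 of 3 samples of the lower group lay well above background. The gene pou5f3 rose by 0.99 ± 0.30 (adjusted p = 0.045). The arrays do not separate its own transcript from the injected mRNA, so its rise is not evidence of a response. The list tests and overlap counts below still include pou5f3 and were not repeated without it.

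Among cell type lists, 3 of 8 enveloping layer genes rose, and 3 when adjusted over the list alone: krt8 (3.95 ± 0.72), krt5 (4.84 ± 0.91) and krt4 (3.66 ± 1.08). The median of that list was 1.87 (adjusted p = 0.033; adjusted p = 0.33 with an estimated correlation). Of 14 p53 genes 7 rose, 9 when adjusted over the list alone, with a median of 0.89 (adjusted p = 2.9e-05; adjusted p = 0.076 with an estimated correlation); foxo3b (2.5 ± 0.48), gadd45aa (3.06 ± 0.70), rrm2b (1.36 ± 0.35) and mdm2 (0.81 ± 0.18) were among them. Of 17 Pou, SoxB1 and Klf factor genes 4 rose, also 4 when adjusted over the list alone, including mycn (2.32 ± 0.68) and pou5f3 itself, with a median of 0.98 (adjusted p = 0.026; adjusted p = 0.64 with an estimated correlation). Of 13 Wnt response genes 3 rose, 4 when adjusted over the list alone, including axin1 (1.13 ± 0.29), with a median of 0.95 (adjusted p = 0.013; adjusted p = 0.32 with an estimated correlation). Ribosomal protein genes had a median of 0.17 (adjusted p = 0.045; adjusted p = 0.77 with an estimated correlation), and 2 of 65 rose (0 when adjusted over the list alone), rps21 (0.63) and rps13 (0.69). Of 29 cell cycle genes 8 fell and 1 rose (9 and 3 when adjusted over the list alone). Among them, ccnb1 lay at -0.81 ± 0.14, cdc20 at -0.73 ± 0.14, chek1 at -0.99 ± 0.21 and wee1 at 1.15 ± 0.26. The cell cycle list as a whole did not pass (median -0.39, adjusted p = 0.057).

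The other lists did not pass for Pou5f1 without CHX. Of 30 neuroectoderm genes 4 rose and 2 fell (5 and 2 when adjusted over the list alone; median 0.18, adjusted p = 0.56). Among them, sox21a lay at -1.88 ± 0.39 and her3, also in the Notch and her list, at 4.17 ± 1.25. Of 35 immediate early genes 6 rose and 1 fell, the same when adjusted over the list alone (median 0.1, adjusted p = 0.45), among them snai2 (3.53, with another probe at -0.87) and btg1 (1.28). Of 9 germline genes ddx4 rose (0.85 ± 0.23) and nanos3 (-1.20 ± 0.26) and h1m (-0.72 ± 0.19) fell (median -0.16, adjusted p = 0.51). Of 20 maternal mRNAs 1, pou5f3 itself, rose and 3 fell, among them btg4 (-1.48) and rbpms2b (-1.06, with another probe at 0.79) (1 and 4 when adjusted over the list alone; median -0.2, adjusted p = 0.39). Single members passed among yolk syncytial layer genes (gata6, 3.34 ± 0.81; median 1.47, adjusted p = 0.071) and ventral genes (dlx3b, 1.71; 0 when adjusted over the list alone; median 0.94, adjusted p = 0.13). Hox and late genes had 2 rises and 1 fall of 20 (median -0.26, adjusted p = 0.88) and histones 1 and 1 of 10 (median -0.35, adjusted p = 0.56). Notch and her genes had a median of -0.06 and a mean of 0.46 (adjusted p = 0.9). The adjusted p was 0.13 for ribosome biogenesis (2 rises and 4 falls of 39), 0.65 for translation factors (1 and 2 of 29) and 0.99 for stress genes (0 and 1 of 16). No member passed with all 18 samples among 27 mesendoderm (adjusted p = 0.64), 15 organizer (median -0.34, mean 0.07, adjusted p = 0.87) and 14 FGF response genes (adjusted p = 0.45).

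With limma, 1119 of 10742 genes passed for Pou5f1 without CHX, 558 higher and 561 lower, 381 and 339 of them over 2-fold. The 2 groups carry opposite dyes and lie on different slides, so dye and slide cannot be separated from Pou5f1 here. The share of higher genes was 49.9%, against 71.6% on the series matrix, and the count was 281 without MZ replicate 1, 386 without MZ replicate 2, 460 without MZ with Pou5f1 replicate 3, 578 without its replicate 1, 2775 with only the groups compared and 6319 with sample weights. MZ replicates 1 and 2 were nearly identical (correlation 0.996), and if they are 1 pool the MZ group has n = 2; with them averaged, an alternative chosen after seeing the data, the count was 351.

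**Figure D2:**
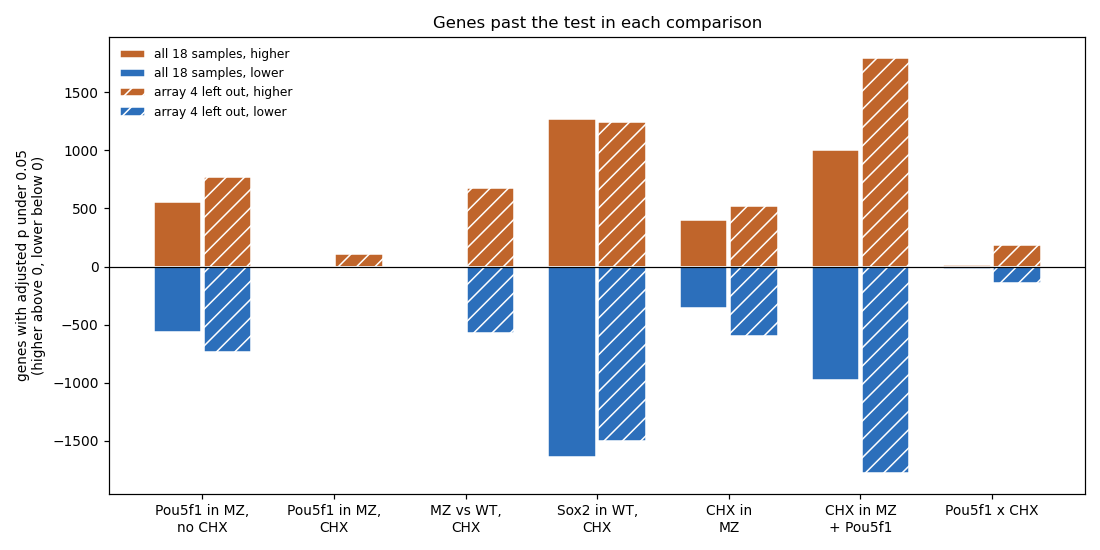
Genes that passed the test in each comparison, higher above the axis and lower below it, with all 18 samples and without array 4.

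Injection of Pou5f1 into CHX-treated MZ embryos asks which genes respond without new protein synthesis. With all 18 samples 5 of 10399 genes passed, 4 higher and 1 lower. The genes gadd45gb.1 (6.60 ± 1.13, 96.8-fold, chromosome 21), ascl1a (5.03 ± 0.70, 32.8-fold, adjusted p = 0.024) and sox2 (2.82 ± 0.47, 7.06-fold) rose, where gadd45gb.1 and sox2 lay just under the threshold. The remaining 2 carry uninformative names, fall outside the naming rule and were named after seeing the values: wu:fj48c04 rose by 3.45 ± 0.53 and TC290438 fell, at -2.25 ± 0.35. The gene pou5f3 differed by 0.89 ± 0.30 (adjusted p = 0.44). Without array 4, 116 genes passed, 104 higher and 12 lower, including all 5. Then the injected samples all lie on slide 1 and the controls on slide 2, scanned without extended dynamic range, so slide and scan cannot be separated from Pou5f1. The largest rises there were in klf17 (7.89 ± 0.38, 238-fold, adjusted p = 5.5e-08), gadd45gb.1 (7.12 ± 0.39), foxd3 (at least 53.1-fold), foxb1a (6.39 ± 0.84), apoeb (6.06 ± 0.59), has2 (5.92 ± 0.80), ascl1a (5.57 ± 0.67) and sp5l (5.30 ± 0.76). They were followed by lfng (4.89 ± 0.48), fzd8a (4.86 ± 0.39), epyc (at least 19.7-fold) and her3 (at least 14.3-fold), while pou5f3 rose by 1.24 ± 0.20 and sox2 by 2.87 ± 0.51. The falls without array 4 were pdgfaa (at least 32.7-fold), spo11 (-3.12 ± 0.56), magt1 (-1.36), suclg1 (-1.28), ap1m2 (-1.10) and rsrc1 (-0.95).

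Slide 1 holds 1 uninjected control with CHX, the deviating sample of array 4, so medians on slide 1 alone rest on it. Of 28 neuroectoderm genes 2 rose with all 18 samples, 3 when adjusted over the list alone, and the list shifted up (median 0.43, adjusted p = 9.3e-06; adjusted p = 0.025 with an estimated correlation). Within slide 1 alone its median was 0.54, and with slide as a block 0.48. Of 17 Pou, SoxB1 and Klf factor genes 1 rose, 7 when adjusted over the list alone, with a median of 0.96 (adjusted p = 1.4e-08; adjusted p = 0.089 with an estimated correlation), 1.24 with slide as a block and 0.26 on slide 1 alone. Without array 4, 8 of these 17 rose, pou5f3 included and among them klf2b (4.78 ± 0.68), klf17 and klf2a (1.27), with a median of 1.27 (adjusted p = 1.2e-38; adjusted p = 4.7e-07 with an estimated correlation). Immediate early genes (0 of 36 passed, 1 when adjusted over the list alone) had a median of 0.42 (adjusted p = 0.00018; adjusted p = 0.089 with an estimated correlation) and 0.29 on slide 1 alone. Ventral genes (0 of 16) had a median of 0.48 (adjusted p = 0.015; adjusted p = 0.41 with an estimated correlation) and -0.26 on slide 1 alone. The medians of p53 genes (0.21, adjusted p = 0.0095; adjusted p = 0.28 with an estimated correlation) and of ribosome biogenesis genes (-0.16, adjusted p = 0.0028; adjusted p = 0.18 with an estimated correlation) were small, at 0.09 and -0.23 on slide 1 alone. Ribosomal protein genes lay at -0.1 (adjusted p = 0.01; adjusted p = 0.42 with an estimated correlation) and -0.13 on slide 1 alone. Enveloping layer genes lay at -0.77 (adjusted p = 0.041; adjusted p = 0.35 with an estimated correlation), and at -1.88 on slide 1 alone.

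With all 18 samples no member of the remaining lists passed among all genes for Pou5f1 with CHX. Their adjusted p values were 0.093 for germline, Wnt response and Notch and her genes, 0.37 for yolk syncytial layer, mesendoderm, Hox and late and stress genes, 0.31 for FGF response and cell cycle genes, 0.61 for the organizer, 0.35 for maternal mRNAs, 0.81 for histones and 0.93 for translation factors (median 0.01, mean -0.01). Members that rose without array 4 include sfrp1a (4.23 ± 0.39), fgfr4 (4.44), dusp6 (4.13 ± 0.67), cdx4 (3.50), lhx5 (3.23), hspb1 (3.35), snai2 (2.60), foxi1 (2.57), cxcr4a (2.48), ved (2.38), id1 (1.94) and h1m (0.88, saturated in both controls).

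With limma, 771 genes had an unadjusted p under 0.05 for Pou5f1 with CHX, and both groups carry Cy5. Without single samples the count was 0 (MZ with CHX replicate 1, or MZ with CHX and Pou5f1 replicate 1 or 2), 1 (MZ with CHX replicate 2, or MZ with CHX and Pou5f1 replicate 3) and 34 (MZ with CHX replicate 3), with slide as a block 9, with sample weights 1452 and with MZ replicates 1 and 2 averaged 2. On slide 1 alone it was 980, where the only control is the sample labelled MZ with CHX replicate 3 of array 4. The share of higher genes was 80%, against 100% after normexp correction and 66.7% on the series matrix.

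MZ against WT embryos, both with CHX, asks what the mutant lacks before new proteins are made. With all 18 samples no gene was named by the rule. The differences were 0.15 ± 0.31 for pou5f3 (adjusted p = 0.95) and 0.92 ± 0.50 for sox2 (adjusted p = 0.82). Without array 4, 1248 genes passed, 677 higher and 571 lower in MZ. The lower ones included klf17 (-7.05 ± 0.34, adjusted p = 6.5e-08), apoeb (-5.85 ± 0.54), gadd45gb.1 (-5.75 ± 0.35) and foxb1a (-5.55 ± 0.76), and further spag7 (-8.08 ± 1.15), sulf2a (-6.72 ± 1.34), ndrg1b (-6.47 ± 1.07), hadhb (-6.31 ± 1.01), ndrg3a (-6.12), gpx4b (-6.11), dcaf13 (-5.91) and xylb (-5.10). Higher in MZ were mrpl43 (at least 41.8-fold), itih2 (at least 19.3-fold), cdk5 (at least 11.5-fold), slc39a13 (5.46 ± 0.96, saturated in both MZ samples), smox (4.88 ± 1.14), cyp2v1 (4.55 ± 0.73, with another probe at -0.56) and kcnip3b (3.95 ± 0.44). The others were klhl31 (at least 9.63-fold), itgb1b.2 (at least 7.66-fold), abi1a (at least 6.24-fold), slc44a4 (3.95) and tmem192 (3.79). Without array 4, pou5f3 differed by -0.55 ± 0.18 (adjusted p = 0.06).

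Of 7 Notch and her genes 0 passed with all 18 samples, 2 when adjusted over the list alone, and the list was higher in MZ (median 1.32, adjusted p = 0.00052; adjusted p = 0.0098 with an estimated correlation); on slide 2 alone its median was 0.4. Without array 4, her6 (1.42) and hey1 (1.45) passed. The other lists below also had 0 members past the test with all 18 samples. Germline genes were lower (median -0.48, adjusted p = 0.00068; adjusted p = 0.14 with an estimated correlation), at -0.26 on slide 2 alone. Ribosomal protein genes were higher (median 0.24, adjusted p = 5.2e-07; adjusted p = 0.36 with an estimated correlation), at 0.23 on slide 2 alone. Mesendoderm genes (median 0.53, adjusted p = 0.033; adjusted p = 0.51 with an estimated correlation) turned to -0.05 on slide 2 alone. Pou, SoxB1 and Klf factor genes (median 0.33, adjusted p = 0.046; adjusted p = 0.51 with an estimated correlation) turned to -0.03, and did not pass with slide as a block (adjusted p = 0.057). Histones (median 0.29, adjusted p = 0.046; adjusted p = 0.36 with an estimated correlation; 2 of 9 when adjusted over the list alone) turned to -0.05. Without array 4, 5 Pou, SoxB1 and Klf factor genes were lower in MZ and 1 higher, among them klf2b (-3.72), mych (-1.48), sox19a (-1.25) and klf2a (-0.83), with a list adjusted p = 0.0025 (adjusted p = 0.63 with an estimated correlation). The FGF and Wnt response genes etv4 (-2.46), dusp6 (-2.58) and sp5l (-3.40), and foxa2 (-2.85), cdx4 (-2.90), krt5 (-2.01), sesn3 (-2.84) and hspb1 (-2.99) were also lower there, and ddit4 (1.46), junbb (2.05) and rps12 (1.13) higher. The other lists did not pass, with adjusted p = 0.06 for ventral genes, 0.1 for the organizer, 0.14 for the enveloping layer, 0.23 for cell cycle, 0.25 for neuroectoderm, maternal mRNAs and p53, 0.31 for yolk syncytial layer and Wnt response, 0.49 for FGF response, Hox and late, stress and translation factor genes, 0.68 for ribosome biogenesis and 0.7 for immediate early genes.

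With limma, 0 of 9945 genes passed for MZ against WT and 635 had an unadjusted p under 0.05, the smallest adjusted p being 0.0969. The groups carry opposite dyes on the same 3 arrays; the count was 732 without WT with CHX replicate 3, 75 without MZ with CHX replicate 3, 23 without its replicate 1, 1048 on slide 2 alone and 1704 with sample weights.

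Sox2 mRNA in CHX-treated WT embryos asks which genes respond to Sox2 without new protein synthesis. The transcription factor genes foxa3 (6.72 ± 1.25, chromosome 18), noto (5.97 ± 1.16) and hnf1ba (at least 11.1-fold) rose. Signalling genes that rose were fgfr4 by 6.25 ± 1.44, fgf8a by 4.71 ± 0.64, fgf17 by 5.46, spry4 at least 32.4-fold and sfrp1a at least 20.7-fold. Other rises were net1 (6.51 ± 0.87, chromosome 4), has2 (6.1 ± 1.51), alcamb (5.76 ± 0.64, adjusted p = 1.6e-05), ctsll (at least 34.8-fold) and plekhf1 (at least 19.1-fold). The genes acte1 (-4.70 ± 0.66), acta1a (-4.42 ± 0.79) and actn3b (at least 1.28-fold) fell. Other genes that fell were gnmt (-5.24 ± 0.93), krcp (-4.69 ± 0.54), nfya (-4.05 ± 0.78), naa40 (-4.02 ± 0.51) and decr1 (-3.87 ± 0.28, adjusted p = 4.4e-07). Falls known only as lower limits were eif3s6ip (at least 4.95-fold), jade3 (at least 4.78-fold) and crabp1a (at least 4.23-fold). The changes of foxa3, fgfr4, has2 and alcamb are not exact, since only 1 of 3 WT samples lay well above background. For gnmt, acte1, krcp, acta1a, naa40 and decr1 the same held for the samples with Sox2. Some values moved without array 4. The rises were then 5.72 ± 1.03 for foxa3, 5.75 for net1, 5.25 ± 0.91 for fgfr4, 4.9 for has2, 4.66 ± 0.94 for noto and 4.33 for fgf17. They were at least 21.7-fold for spry4 and at least 21.3-fold for alcamb. The falls were -3.65 for acta1a and at least 2.38-fold for crabp1a. The gene pou5f3 differed by 0.18 ± 0.30 (adjusted p = 0.68), and sox2, not tested in either fit, had a mean at least 4.74-fold higher without array 4.

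Lists of patterning genes shifted up with Sox2 under the preset correlation. Of 20 mesendoderm genes 16 rose, 16 also when adjusted over the list alone, with a median of 2.36 (adjusted p = 7e-07; adjusted p = 0.15 with an estimated correlation). They included wnt8a (1.79 ± 0.25), lft2 (2.30) and ndr1 (1.99). Of 18 neuroectoderm genes 10 rose, 10 when adjusted over the list alone (median 2.38, adjusted p = 0.00015; adjusted p = 0.12 with an estimated correlation). They included fezf2 (4.21), gbx1 (3.53), her9 (3.37) and irx1b (3.05). Of 12 organizer genes 9 rose, 9 when adjusted over the list alone (median 2.22, adjusted p = 0.00035; adjusted p = 0.2 with an estimated correlation). They included chrd (2.89). Of 12 ventral genes 6 rose and 1 fell (median 1.54, adjusted p = 0.0052; adjusted p = 0.28 with an estimated correlation). Among them, gata2a lay at 3.88, gata3 at 3.21, bambia at 3.12 and vox at 2.01. All 5 yolk syncytial layer genes rose (median 3.56, adjusted p = 0.0024; adjusted p = 0.19 with an estimated correlation). They included mxtx1 (4.17), gata6 (3.56) and mxtx2 (1.79). Of 13 FGF response genes 8 rose and 1 fell (9 and 1 when adjusted over the list alone; median 1.5, adjusted p = 0.0013; adjusted p = 0.24 with an estimated correlation). Among them, etv5a lay at 1.5. Of 12 Wnt response genes 8 rose, 11 when adjusted over the list alone (median 2.09, adjusted p = 2e-05; adjusted p = 0.077 with an estimated correlation). They included ccnd1 (5.21). Of 8 Notch and her genes 6 rose and 1, notch1a (-0.98), fell (median 2.97, adjusted p = 0.001; adjusted p = 0.077 with an estimated correlation), led by hey1 (4.72 ± 0.46) and her6 (3.45 ± 0.39). Of 12 Pou, SoxB1 and Klf factor genes 5 rose, 6 when adjusted over the list alone (median 2.04, adjusted p = 0.0073; adjusted p = 0.34 with an estimated correlation). They included mycn (3.57), sox3 (3.47) and klf2a (2.25). Rises of list members that were smaller without array 4 were those of fezf2 (3.44), mxtx1 (2.92), sox3 (2.58), chrd (2.19), lft2 (1.65), klf2a (1.57), vox (1.41) and mxtx2 (1.14). Without array 4 only lower limits were known for mycn (at least 5.64-fold), her9 (at least 5.09-fold) and gata6 (at least 3.32-fold).

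Of 6 Hox and late genes 2 rose, 4 when adjusted over the list alone (median 1.06, adjusted p = 0.028; adjusted p = 0.094 with an estimated correlation). They included lhx5 (3.72, and 2.66 without array 4). Of 32 immediate early genes 13 rose and 5 fell (14 and 5 when adjusted over the list alone; median 0.84, adjusted p = 0.018; adjusted p = 0.27 with an estimated correlation). Among them, jun lay at 3.58, ier5 at 2.82 and btg2 at -1.71. Of 63 ribosomal protein genes 26 rose and 8 fell (27 and 8 when adjusted over the list alone; median 0.47, adjusted p = 0.00036; adjusted p = 0.28 with an estimated correlation). Among them, rpl26 lay at 1.56 and rps14 at -1.76. Of 12 p53 genes 5 rose and 1 fell (median 0.63, adjusted p = 0.048; adjusted p = 0.34 with an estimated correlation). Among them, phlda3 lay at 2.95 (2.07 without array 4), foxo3b at 2.39 and ccng1 at -1.14. Lists that did not pass were cell cycle genes (6 rises and 9 falls of 27; median -0.35, mean 0.17, adjusted p = 0.54), with mcm3 at 2.58, ccna2 at -1.77 and ccnb1 at -1.35 (saturated in 1 of 3 WT samples), and the enveloping layer (2 and 1 of 6, adjusted p = 0.31), with krt4 at 4.78 and krt18a.1 at 4.15. Germline genes (0 and 1 of 9, adjusted p = 0.23) had dazl at -1.51. Maternal mRNAs (3 and 3 of 19) had an adjusted p = 0.9, stress genes (4 and 1 of 16) 0.22, translation factors (5 and 7 of 29) 0.7, and histones (2 and 1 of 8) 0.7. Ribosome biogenesis genes (5 and 6 of 35) had a median of -0.03 and a mean of 0.05 (adjusted p = 0.96). Among them, nop56 lay at 1.37 and ncl at -1.43 (saturated in 1 of 3 WT samples).

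With limma, 2912 of 7671 genes passed for Sox2, 1271 higher and 1641 lower, 761 and 1063 of them over 2-fold, and 2743 passed without array 4. The count was 883 with only the groups compared, 446 higher and 437 lower, and 1883 with sample weights. The Sox2 samples lie on their own slide with the widest spread between spots, so slide and Sox2 cannot be separated.

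**Figure D3:**
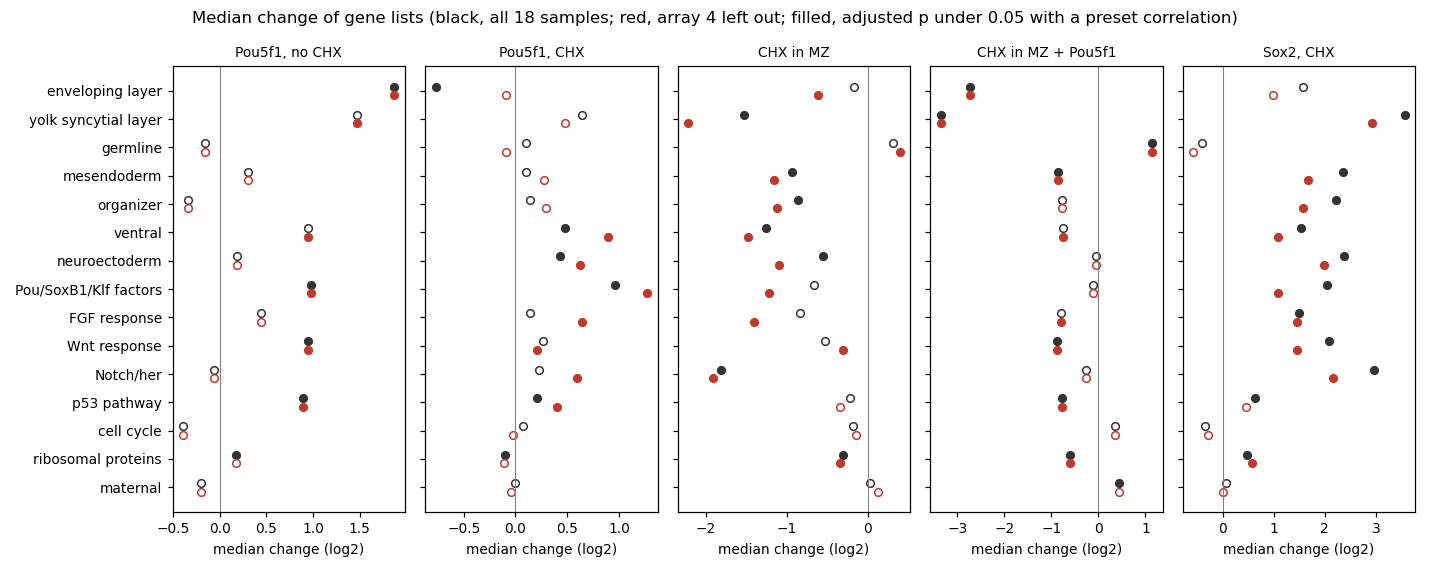
Median log2 change of 15 gene lists in 5 comparisons, with all 18 samples (black) and without array 4 (red). Filled points had adjusted p under 0.05 with the preset correlation.

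CHX in uninjected MZ embryos asks what protein synthesis contributes to expression without functional Pou5f1. The samples without CHX lie on a slide of their own, extracted with another protocol, so slide and protocol cannot be separated from CHX here. The transcription factor genes dbx1a (-5.20 ± 0.47, adjusted p = 6.4e-05, chromosome 7), nr2f1a (-4.48 ± 0.73), fezf2 (-4.48 ± 0.78) and her9 (-3.45 ± 0.63) fell. Also lower were hel_dr5 (-5.32 ± 0.71), gnb3a (-4.45), lmbr1l (-4.30 ± 0.63), atp1a1b (-4.07), sfrp1a (-3.81 ± 0.81), gbgt1l4 (-3.78), cited4a (-3.50 ± 0.47) and pcdh10b (-3.38 ± 0.53). Rises were seen in dnase1l1 (5.78 ± 0.91), tspan18a (4.63 ± 1.08), hdac9b (4.30 ± 0.83), pes (3.88 ± 0.65, chromosome 24), spata4 (3.69 ± 0.82), atp6ap1b (3.19 ± 0.44) and cdx4 (3.16 ± 0.88). The remaining rises were pde6ha (2.91), med19b (2.68 ± 0.38), itm2bb (2.64 ± 0.45), hirip3 (2.36 ± 0.27, saturated in 1 of 3 samples with CHX) and acox3 (at least 6.57-fold). The changes of dnase1l1, hel_dr5, dbx1a and pcdh10b are not exact, since only 1 of 3 samples of the lower group lay well above background. The gene pou5f3 differed by -0.01 ± 0.30 (adjusted p = 0.99) and sox2 by -1.20 ± 0.47 (adjusted p = 0.15). Without array 4 the falls were -5.28 ± 0.39 for sfrp1a, -3.70 for nr2f1a, -3.59 for lmbr1l, at least 24.4-fold for dbx1a and at least 5.48-fold for pcdh10b. The rise of dnase1l1 was 5.12, and gnb3a did not pass (adjusted p = 0.085). Without array 4 the falls also included fzd8a (-5.42), klf17 (-4.45), krt4 (-3.29), gsc (-3.22) and krt8 (-1.75).

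Of 8 Notch and her genes 3 fell, 5 when adjusted over the list alone, including her5 (-2.78 ± 0.55) and hey1 (-2.30 ± 0.46), and the list shifted down (median -1.82, adjusted p = 0.00025; adjusted p = 0.0012 with an estimated correlation). Of 20 Hox and late genes 3 fell, 3 when adjusted over the list alone (median -0.53, adjusted p = 0.005; adjusted p = 0.0053 with an estimated correlation), namely meis1a (-1.70), hoxb8a (at least 2.34-fold) and nkx2.5 (at least 1.63-fold). These lists, with neuroectoderm for Pou5f1 with CHX and the Notch and her genes for MZ against WT, are the 4 that passed with an estimated correlation and all 18 samples, where 52 passed with the preset one. Without array 4 they were 14 and 58. Each of the 4 comes from a comparison that uses samples of array 4. For the Notch and her genes in MZ against WT, the median was 1.32 with all 18 samples. It was 0.4 on slide 2 alone, which does not hold array 4. Of 28 neuroectoderm genes 4 fell (4 and 1 rise when adjusted over the list alone; median -0.55, adjusted p = 0.005; adjusted p = 0.16 with an estimated correlation). They included irx1b (-2.86) and gbx1 (-2). Of 16 ventral genes 3 fell and 1 rose (8 and 2 when adjusted over the list alone; median -1.26, adjusted p = 0.0075; adjusted p = 0.37 with an estimated correlation). Among them, tbx2b lay at -2.30 (adjusted p = 0.063 without array 4), id1 at -2.03 (-2.84 without array 4) and gata3 at -1.80. Of 7 yolk syncytial layer genes mxtx2 fell (-1.38), 4 when adjusted over the list alone (median -1.53, adjusted p = 0.005; adjusted p = 0.25 with an estimated correlation). Of 15 organizer genes nog1 fell (-2.49), 2 when adjusted over the list alone (median -0.87, adjusted p = 0.021; adjusted p = 0.37 with an estimated correlation). Mesendoderm genes had a median of -0.94 (adjusted p = 0.005; adjusted p = 0.38 with an estimated correlation), while mespba alone of 27 passed, and rose (1.12; 2 rises and 3 falls when adjusted over the list alone). Of 65 ribosomal protein genes 7 fell, 9 when adjusted over the list alone (median -0.31, adjusted p = 5.4e-07; adjusted p = 0.23 with an estimated correlation). They included rps15a (-0.88) and rpl17 (-0.74).

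Lists that did not pass for CHX in MZ were immediate early genes (4 falls of 36, adjusted p = 0.073). Among them, jun lay at -1.99, btg1 at -1.31 and ier5 at -1.23, and germline genes (2 rises of 9, adjusted p = 0.071). Among them, ca15b lay at 1.33 and dazl at 1.27 (saturated in 2 of 3 samples with CHX). Maternal mRNAs (3 rises of 20, adjusted p = 0.37) had mos at 1.61 and rbpms2a at 1.27. Enveloping layer genes (krt18a.1, -2.64, and -3.71 without array 4; 1 of 8) had an adjusted p = 0.58, p53 genes (phlda3, -2.33; 1 of 14) 0.31, and stress genes (hsp70.3, -1.03, adjusted p = 0.051 without array 4; 1 of 16) 0.11. Cell cycle genes (2 rises, kif11 at 1.1 and cdk1 at 0.97, and 2 falls of 29) had an adjusted p = 0.45, Wnt response genes (1 and 2 of 13) 0.19 and ribosome biogenesis genes (1 and 1 of 39) 0.97. No member passed with all 18 samples among Pou, SoxB1 and Klf factor genes (adjusted p = 0.069), FGF response genes (0.052), translation factors (0.45) and histones (0.069). Without array 4, klf17 (-4.45), klf2b (-3.91), sox3 (-2.47), klf2a (-1.5), fgfr4 (-5.35), dusp6 (-4.42), fgf17 (-3.83), fgf3 (at least 1.89-fold), h2ax1 (-2.06), hist2h2l (-1.88) and h2ax (-1.48) fell. The adjusted p was then 3.8e-07 for the Pou, SoxB1 and Klf factor genes, 4e-05 for FGF response genes and 0.0021 for histones, and 0.056, 0.071 and 0.056 with an estimated correlation.

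With limma, 754 of 10761 genes passed for CHX in MZ, 399 higher and 355 lower, 277 and 289 of them over 2-fold, between samples that all carry Cy5. The count was 1121 without array 4, 279 without MZ with CHX replicate 1, 301 without MZ replicate 1, 315 without MZ replicate 2, 415 without MZ with CHX replicate 2, 311 with MZ replicates 1 and 2 averaged and 5284 with sample weights.

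CHX in Pou5f1-injected MZ embryos was measured within 3 arrays of slide 1, with opposite dyes. The keratin genes krt4 (-6.72 ± 1.13), krt5 (-6.69 ± 0.96) and krt8 (-6.21 ± 0.75), which mark the enveloping layer, fell. The transcription factor genes hnf4a (at least 32.5-fold, adjusted p = 2e-04) and hnf1ba (-5.37 ± 1.23) fell too. Further falls were those of ctsll (-6.72 ± 1.49), tmsb1 (-6.22 ± 1.34), plekhf1 (-5.62 ± 0.92), anxa1a (-5.61 ± 1.35), insm1b (-5.44 ± 0.73), pitpnc1b (at least 42.3-fold) and ptgs2a (at least 11.2-fold). Rises were seen in gadd45gb.1 (5.55 ± 1.18), slc35c2 (5.55 ± 1.20), cdx4 (4.37 ± 0.92), bgnb (3.67 ± 0.74), tspan18a (3.54 ± 1.13), gchfr (3.43 ± 0.67) and paqr5a (3.43 ± 0.36, chromosome 18). The others were tcf15 (3.28), slc2a3a (3.24), arhgap11a (3.22 ± 0.42), atad5b (3.21 ± 0.27, adjusted p = 9.4e-06) and pfkfb2a (3.17). The changes of slc35c2, bgnb, tcf15 and insm1b are not exact, since only 1 of 3 samples of the lower group lay well above background. For slc35c2 and bgnb these are the same MZ samples with Pou5f1 that gave their falls without CHX. The gene pou5f3 differed by -0.12 ± 0.31 (adjusted p = 0.84) and sox2 by -0.06 ± 0.50 (adjusted p = 0.95).

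Of 8 enveloping layer genes 4 fell (4 and 1 rise when adjusted over the list alone; median -2.74, adjusted p = 0.0013; adjusted p = 0.11 with an estimated correlation), and of 7 yolk syncytial layer genes 5 fell, 5 when adjusted over the list alone (median -3.35, adjusted p = 0.00033; adjusted p = 0.14 with an estimated correlation). They included gata6 (-5.08 ± 0.84). Of 9 germline genes 5 rose and 1 fell (6 and 1 when adjusted over the list alone; median 1.14, adjusted p = 0.0051; adjusted p = 0.16 with an estimated correlation). Among them, ca15b lay at 2.22, nanos3 at 1.66 ± 0.27, dazl at 1.31 and h1m at 1.15. Of 20 maternal mRNAs 8 rose and 1 fell (8 and 2 when adjusted over the list alone; median 0.44, adjusted p = 0.045; adjusted p = 0.14 with an estimated correlation). Among them, btg4 lay at 2.24 and mos at 1.83. Of 65 ribosomal protein genes 24 fell, 40 when adjusted over the list alone (median -0.61, adjusted p = 7e-13; adjusted p = 0.11 with an estimated correlation). They included rpl27 (-1.32), rps15a (-0.99) and rps21 (-0.98). Of 14 p53 genes 5 fell and 1 rose (9 and 1 when adjusted over the list alone; median -0.77, adjusted p = 0.0051; adjusted p = 0.18 with an estimated correlation). Among them, phlda3 lay at -3.05, foxo3b at -2.61 and bcl2l1 at 1.03. Of 25 mesendoderm genes 4 fell and 1 rose (8 and 1 when adjusted over the list alone; median -0.87, adjusted p = 0.021; adjusted p = 0.53 with an estimated correlation). Among them, gata5 lay at -3.10, foxa2 at -2.71 and mespba at 1.96. Of 13 Wnt response genes 4 fell and 1 rose, the same when adjusted over the list alone (median -0.88, adjusted p = 0.021; adjusted p = 0.28 with an estimated correlation). Among them, ccnd1 lay at -3.70 and sp5a at -3.63.

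Lists that did not pass for CHX in injected embryos were ventral genes (2 rises and 4 falls of 17, adjusted p = 0.058). Among them, gata2a lay at -4.10 and dlx3b at least 17.1-fold lower, and neuroectoderm genes (3 and 6 of 29, adjusted p = 0.6). Among them, neurog1 lay at 3.12 and gbx1 at -3.72. Cell cycle genes (8 and 6 of 29; median 0.35, mean -0.02, adjusted p = 0.11) had kif11 at 1.76, cdk1 at 1.34 and wee1 at -1.70. Immediate early genes (5 and 5 of 35; median 0.2, mean -0.17, adjusted p = 0.71) had cebpb at -3.91 and jun at -2.43. Hox and late genes (0 and 3 of 14; median 0.24, mean -0.05) had an adjusted p = 0.48, Pou, SoxB1 and Klf factor genes (0 and 1, mycn at -3.78, of 17) 0.48, and stress genes (2 and 1 of 16) 0.48. The adjusted p was 0.089 for FGF response (0 and 2 of 14), 0.16 for Notch and her (0 and 2, her9 at -2.83 and hey1 at -2.98, of 9), 0.29 for organizer (1 and 0 of 14), 0.36 for translation factor (1 and 3 of 29), 0.43 for histone (1 and 2 of 10) and 0.91 for ribosome biogenesis genes (2 and 3 of 39).

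With limma, 1978 of 10426 genes passed for CHX in injected embryos, 1003 higher and 975 lower, 709 and 672 of them over 2-fold, and 3569 passed without array 4. Neither group has a sample on array 4, but the spread of each gene is estimated over all 6 groups. For krt4 the change was -6.72 in both fits. Its error was 1.13 with all 18 samples and 0.51 without array 4. The count was 1092 without MZ with CHX and Pou5f1 replicate 3, 1316 without its replicate 1, 1176 without MZ with Pou5f1 replicate 3, 1180 without its replicate 1, 4551 with only the groups compared and 6170 with sample weights, and dye cannot be separated from CHX here.

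The interaction asks whether the response to Pou5f1 differed with and without CHX. Of the groups compared, only MZ with Pou5f1 carries Cy3, and MZ lies on its own slide, extracted with another protocol. Dye, slide and protocol therefore cannot be separated from the interaction, with or without array 4. For krt8 the change with Pou5f1 was 3.95 without CHX and -1.68 with it, a difference of -5.64 ± 1.04, and for krt5 the difference was -7.02 ± 1.33. The h1m response was -0.72 without and 0.82 with CHX, a difference of 1.54 ± 0.28, with 2 of 3 MZ samples with CHX saturated. For pou5f3 the difference was -0.11 ± 0.43 (adjusted p = 0.95) and for sox2 1.14 ± 0.68 (adjusted p = 0.5). Enveloping layer genes differed as a list (median -2.45, adjusted p = 0.00091; adjusted p = 0.13 with an estimated correlation), with 2 of 8 members past the test, 3 when adjusted over the list alone. Ribosomal protein genes (median -0.3, adjusted p = 0.00091; adjusted p = 0.58 with an estimated correlation), p53 genes (median -0.64, adjusted p = 0.027; adjusted p = 0.48 with an estimated correlation) and cell cycle genes (median 0.48, adjusted p = 0.019; adjusted p = 0.13 with an estimated correlation) had 0 members past the test, and the other lists did not pass. Without array 4 the differences for krt5 and krt8 were -5.79 and -4.46, and lin28ab (5.53), foxd3 (4.64), fzd8a (4.64), klf2b (4.46) and gadd45gb.1 (4.40) passed as well, with slide and scan not separated from Pou5f1.

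With limma, 33 of 10967 genes passed for the interaction, 13 higher and 20 lower with CHX, and 1556 had an unadjusted p under 0.05. Higher genes made up 39.4% of them, against 54.3% after normexp correction and 50% after scaling to the 75th percentile. The count was 327 without array 4, 209 without MZ with CHX replicate 3, 71 without MZ replicate 3, 82 without MZ with Pou5f1 replicate 2, 92 with slide as a block, 1022 with only the groups compared and 4394 with sample weights. It was 1 without MZ replicate 1, MZ replicate 2 or MZ with CHX and Pou5f1 replicate 3, and 1 with MZ replicates 1 and 2 averaged.

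The response to Pou5f1 with CHX was compared with WT over MZ, with Sox2 and with Pou5f1 without CHX, 3 overlaps planned to look for direct targets. With all 18 samples, ascl1a (5.03 with CHX, 7.23 without) and sox2 (2.82 and 1.68) rose with Pou5f1 both with and without CHX, 2 genes where 0.2 were expected (Fisher's exact test, p = 0.0139), and 1 gene changed in opposite directions. None could be shared with WT over MZ, where 0 genes passed. With Sox2 none was shared, but only 1 rise and 1 fall with Pou5f1 were tested in both comparisons. There 0.2 shared rises and 0.2 shared falls were expected, so this says little. Without array 4, 44 genes changed the same way with Pou5f1 and in WT over MZ, both with CHX. They were 41 rises, where 4.3 were expected, and 3 falls, where 0.8 were, and 3 changed in opposite directions. They included klf17 (7.89 with Pou5f1 and 7.05 in WT over MZ), gadd45gb.1 (7.12 and 5.75), fzd8a (4.86 and 5.09), apoeb (6.06 and 5.85), lfng (4.89 and 4.45), foxb1a (6.39 and 5.55), sp5l (5.30 and 3.40) and klf2b (4.78 and 3.72). Also shared were bpgm (3.68 and 4.53), igf2a (3.30 and 2.69), cxcr4b (2.43 and 1.70) and fn1a (2.22 and 1.60). The MZ samples with CHX are the control of both comparisons, and 3 controls are too few to give each its own. In 20 simulations without a shared response the correlation was 0.45, where 0.33 was observed, and the covariance 0.091, where 0.185 was observed. With all 18 samples these correlations were 0.52 and 0.04.

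Pou5f1 and Sox2, both with CHX, shared 35 genes without array 4. They were 34 rises, where 12.7 were expected, and 1 fall, where 2.2 were (Fisher's exact test, p = 0.909), and 8 changed in opposite directions. Among the shared rises were sfrp1a (4.23 with Pou5f1 and at least 13.9-fold with Sox2), has2 (5.92 and 4.90), dusp6 (4.13 and 2.79), her3 (at least 14.3-fold and 2.66), igf2a (3.30 and 1.99), drl (3.06 and 3.14), ved (2.38 and 1.53) and klf2a (1.27 and 1.57). The others were apoeb (6.06 and 2.1), fzd8a (4.86 and 1.45), nfatc2ip (2.49 and 1.37) and efna1b (2.48 and 1.45). Without array 4 the controls of both lie on slide 2 and the injected samples on others, so a slide 2 effect would be shared too. The responses to Pou5f1 with and without CHX shared 42 genes without array 4. They were 38 rises, where 7.1 were expected, and 4 falls, where 0.8 were, and 8 were opposite. These included ascl1a (5.57 with CHX and 7.23 without), sp5l (5.30 and 5.63), epyc (at least 19.7-fold and 5.57), her3 (at least 14.3-fold and 4.17), klf17 (7.89 and 4.09), foxb1a (6.39 and 3.63), has2 (5.92 and 3.28), apoeb (6.06 and 3.06), igf2a (3.30 and 2.90), gadd45gb.1 (7.12 and at least 4.9-fold), ved (2.38 and 1.51) and pou5f3 (1.24 and 0.99), which the injected mRNA itself would raise if its probe reads it. Both comparisons are then between slides, with all injected samples on the same 3 arrays of slide 1, so a slide 1 effect would be shared too. The correlations of changes were 0.23 for Sox2 and 0.25 for Pou5f1 without CHX, where simulations gave 0.19 and 0.14. When a single sample was left out of the 18, the shared counts ranged from 0 to 2 for WT over MZ, 0 to 12 for Sox2 and 0 to 13 for Pou5f1 without CHX, the highest values of 12 and 13 without MZ with CHX replicate 3.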

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

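The tests on array 4, on the series matrix columns and on a deviating array among the controls were chosen after seeing the result. The interaction was planned and flagged 33 genes whose response to Pou5f1 differed between embryos with and without CHX. Dye, slide and protocol cannot be separated from these differences.

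Among named genes the difference was negative, that is lower with CHX, for dnase1l1 (-7.37 ± 1.31), krt5 (-7.02 ± 1.33), krt8 (-5.64 ± 1.04), ptgs2a (-4.84 ± 0.86), itm2bb (-3.56 ± 0.66), prph (-3.45 ± 0.69), zdhhc16b (-2.27 ± 0.35), tjp3 (-1.89 ± 0.33), tmem144b (-1.66 ± 0.33) and ybx1 (-1.37 ± 0.26). It was positive for lmbr1l (4.81 ± 0.91), trpc4apb (3.65 ± 0.67), slmapb (2.92 ± 0.51), evla (2.08 ± 0.39), mibp (1.85 ± 0.37), use1 (1.65 ± 0.31), h1m (1.54 ± 0.28) and usf1 (1.49 ± 0.30). Without array 4 it was -6.71 for dnase1l1, -5.79 for krt5, -4.46 for krt8 and 4.1 for lmbr1l. The differences of ptgs2a and prph are not exact, since these genes lay well above background in all 3 MZ samples with Pou5f1 but in 0 of 3 with CHX and Pou5f1 and 1 of 3 in the other groups. In MZ without CHX, 1 of 3 samples was well above background for dnase1l1 and 2 of 3 for itm2bb. In MZ with CHX, 2 of 3 samples were saturated for h1m. Of 100 splits of the 12 samples into 4 groups, 2 gave at least as many genes, the real one included, and the highest other gave 272. These splits also mix the effects of Pou5f1 and of CHX, and a split can turn one of those effects into the interaction. They are therefore no test of the interaction alone.

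The samples labelled WT with CHX replicate 3 and MZ with CHX replicate 3, on array 4, lay nearer to the other group. Of 1265 genes that differed by over 1 log2 unit between genotypes on arrays 5 and 6, 80% differed the opposite way on array 4. This is at the limit set, after seeing the data, for an exchange of labels or dyes, so this test alone cannot tell. On a scale from 0 (MZ) to 1 (WT), the median was 0.08 (quartiles -0.1 to 0.33) for the sample labelled WT and 0.72 (0.35 to 1.02) for the sample labelled MZ. A dye effect shared by arrays 4 to 6 would keep the direction on array 4, but only 20% differed the same way. This 20% and the 80% describe the same genes, so they are not separate tests. A shift of slide 1 shared by the channels cancels in their difference. That difference on array 4 correlated at -0.49 with the mean of arrays 5 and 6. Neither of these alone accounts for the reversal. A dye effect that differs between slides or scans was not tested. By correlation each sample of array 4 lay closer to replicates 1 and 2 of the other genotype with CHX than to those of its own label. The samples were kept as labelled. The count of 0 for MZ against WT with all 18 samples is thus no evidence that the genotypes do not differ.

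More genes passed for Pou5f1 without CHX, between opposite dyes, than with CHX, within 1 dye. A gene-specific dye effect stays open: 39.7% of 1013 genes that passed, and 45% of all genes, had the sign of the dye difference, but this estimate is free of genotype only if the labels of array 4 were exchanged. Without array 4 the count with CHX was 7.7% of that without. The control group with CHX then holds 2 samples, and the count without CHX was 351 with MZ replicates 1 and 2 averaged (array 4 kept). A deviating array among the controls is therefore not excluded. A slide or scan setting difference also stays open, with 0 slides that hold both groups.

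The series matrix columns of the Sox2 samples did not match the scanner files of the same name. An exchange of replicates 2 and 3 fits, with the lower crossed correlation at 0.993. The replicate 1 column correlated best, at 0.973, with the replicate 3 file and at 0.926 with its own. The mean signal was compared after normexp background correction. Then 0 of 3 columns were closer to that of any Sox2 file (at most 0.914) than to the best processed signal. The uncorrected mean signal was not compared, so a matrix made from it is not excluded.

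In splits of each 6 samples into 3 and 3, too few (10) for a share under 0.05, the real count of 1119 for Pou5f1 without CHX stood against a highest other of 0, 5 for Pou5f1 with CHX against 2, and 2912 for Sox2 against 70. It was 754 for CHX in MZ against 26, and 1978 for CHX in injected embryos against 0, each with 1 split as large, the real one. For MZ against WT the real count was 0, so all 10 splits had to give at least as many and their number says nothing. The highest other gave 719, with WT replicates 1 and 2 and the sample labelled MZ with CHX replicate 3 on one side.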

How the results depend on the processing

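The 5 alternatives that leave out array 4, average MZ replicates or use a single slide were chosen after seeing the data. Named genes were refitted with normexp, the 75th percentile, the matrix, each block, array 4 left out and single samples left out (2428 comparisons the same, 153 stronger, 317 weaker). None reversed, but this was largely set by the naming rule, which took genes that passed without overlap between replicates. A gene or list that passed in neither fit counted as the same whatever its sign. Of the list shifts 3 reversed (777 the same, 26 stronger, 76 weaker). Of the counts, 125 stayed and 111 moved, and the cause was not tested unless fewer samples or genes show it. A count stayed when it lay within a set ratio of the main one, not only when it was equal. For Pou5f1 without CHX, 891 at the 75th percentile against 1119 counted as staying. The series matrix was run only for the first 4 comparisons, since its sets do not connect the others; without array 4 it gave 2220, 269, 2193 and 3553 genes.

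Counts that moved are given in the order of the comparisons. Only the groups compared: 2775 (Pou5f1 without CHX), 883 (Sox2), 4551 (CHX with Pou5f1) and 1022 (interaction). Sample weights gave 6319, 1452, 1704, 1883, 5284, 6170 and 4394, and shared 209 (WT over MZ), 182 (Sox2) and 519 (without CHX). Array 4 left out gave 116 (Pou5f1 with CHX), 1248 (MZ against WT), 3569 and 327, shared 44, 35 and 42, and reversed MZ against WT medians for mesendoderm (-0.05), Pou, SoxB1 and Klf factors (-0.03) and histones (-0.05). Array 4 and Sox2 left out gave 3598, 468, 2759, 2839 (CHX in MZ), 5004 and 1698, shared 160 and 156 (without CHX). MZ replicates 1 and 2 averaged gave 351, 2, 311 and 1, shared 1; the arrays do not show whether they are separate pools. Pou5f1 with CHX gave 30 on the matrix (shared 3 and 10), 0 with no dim filter, 2 with the strict one, 3 with outlier spots kept, 3 with a replicate block, 9 with a slide block and 980 on slide 1 alone. MZ against WT gave 50 with no dim filter, 19 at the 75th percentile, 1 with the mean over probes and 1048 on slide 2 alone. Sox2 gave 4552 with no dim filter, and CHX with Pou5f1 3680 by log ratios. The interaction gave 122 with no dim filter, 3 with the strict one, 92 with a slide block and 61 with no array block. Shared with and without CHX were 4 with no array block, 0 with no dim filter and 1 with the strict filter, outlier spots kept, the slide block or the 75th percentile, and shared with Sox2 2 with the slide block. List calls were 4 with the estimated correlation, of 52, and 14 of 58 without array 4.

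Without single samples counts ranged from 281 (MZ replicate 1) to 887 (MZ replicate 3) for Pou5f1 without CHX, 0 to 34 (MZ with CHX replicate 3) for Pou5f1 with CHX, 0 to 732 (WT with CHX replicate 3) for MZ against WT and 2300 to 3418 for Sox2. They ranged from 279 (MZ with CHX replicate 1) to 991 (its replicate 3) for CHX in MZ, 1092 (MZ with CHX and Pou5f1 replicate 3) to 1841 (MZ with Pou5f1 replicate 2) for CHX with Pou5f1 and 1 to 209 for the interaction, and shared counts reached 2, 12 and 13.

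The replicate block gave 977, 0, 2786, 630, 2143 and 42 for the other comparisons and 48 list calls, the 0 for MZ against WT being unchanged. Same-number samples did not pair (no comparison had every sample correlate best with its own number). Median changes over 0.1 arose at the 75th percentile (-0.11 for Pou5f1 without CHX, 0.13 for the interaction) and on the matrix (0.11, and -0.18 for Sox2). Named genes weakened most without MZ replicate 1 (41 of 109) and MZ replicate 2 (39). Signal over background limits Sox2 most (36.3% of probes in 1 sample).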

Other observations

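The test of immediate early genes was written before its result was seen, and the other values in this part involve no test. The hypothesis was that blocking translation stabilises short-lived mRNAs, so that over 75% of these genes would lie higher with CHX in MZ embryos. Of 36 tested, 33.3% were higher, and 41.7% without array 4, so the predicted share was not reached. Slide and protocol cannot be separated from CHX in this comparison, so the result does not exclude that short-lived mRNAs are stabilised.

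The 3 replicates of MZ without CHX were uneven: replicates 1 and 2 correlated at 0.996 and each at 0.962 with replicate 3. The SD of the log2 difference between replicates 1 and 2 was 0.225, where the spots alone gave 0.143, and does not show whether they are separate pools. The mean correlation with the other samples of its group was 0.911 for the sample labelled WT with CHX replicate 3, against 0.946 with MZ with CHX, and 0.91 for the sample labelled MZ with CHX replicate 3, against 0.931 with MZ with CHX and Pou5f1. Among single samples, the sample labelled MZ with CHX replicate 3 correlated at 0.938 and 0.943 with WT with CHX replicates 1 and 2 and at 0.903 and 0.917 with MZ with CHX replicates 1 and 2. The sample labelled WT with CHX replicate 3 correlated at 0.982 and 0.96 with those MZ replicates and at 0.916 and 0.905 with those WT replicates. Sox2 replicate 1 had 0.888 with its own group and 0.928 with MZ with CHX and Pou5f1. The array weights were 0.24 and 0.26 for the samples of array 4, 0.15, 0.17 and 0.38 for Sox2, and 6.49 for MZ with Pou5f1 replicate 3.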
